A study of Rattus norvegicus with 28 samples.

How the data were processed

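The series holds 28 samples of NRK-49F rat kidney fibroblasts, of which 8 are RNA-seq libraries of polyadenylated RNA in 4 groups of 2 (control, TGF-β, TGF-β with MetR, TGF-β with siHoxc8) and 20 are chromatin immunoprecipitation and input samples. Per the labels' protocols, cells were grown with 10% serum, starved for 24 h in 0.2% serum, and given TGF-β1 at 5 ng per uL, the unit the labels print, for 48 h. The restriction medium was built from Eagle's salts, vitamins, dialyzed serum and amino acids, with methionine at 30 uM, against 200 uM in its control medium, per the labels' protocols. Groups were taken from the sample titles, which give 48 h for the RNA-seq libraries with TGF-β and no time for the control libraries.

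The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the size of the library) with gene symbols for all 8 libraries, per the labels. Trim Galore, Bowtie2 2.3.5.1, deepTools and featureCounts are listed for the series without their roles, with the rat genome build rn6, per the submitters' processing notes. Which of these steps the RNA-seq reads went through, the gene annotation, the strand setting of the counting and the total behind the FPKM values are not given in the sources used here. The table lists 30178 genes, of which 19435 were above 0 in at least 1 library and 10743 were listed at 0 in every library. All 13 mitochondrially encoded genes were listed at 0, so a 0 is reported only as listed and no fold is given against a group at 0. A total of 17436 symbols were found in the RefSeq gene table, which was used for names alone.

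Depth was read from the values. In each library the values of a gene were whole multiples of 1 step, and dividing by it gave whole reads for 100.0% of the 19435 genes above 0 (tolerance 0.02 reads). The reads recovered numbered 15118113 to 20146870 per library, a ratio of 1.33 between the highest and the lowest, and held 99.9% of the total behind the FPKM values. The SD between replicates on the log2 scale was 0.177 for control, 0.223 for TGF-β, 0.307 for TGF-β with MetR and 0.186 for TGF-β with siHoxc8, and 152, 162, 372 and 166 genes differed at least 2-fold between the replicates of these groups.

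Expression was compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as a linear model over all 8 libraries with 1 coefficient per group, no covariates, and moderated variances with a trend on mean expression. All groups share 1 estimate of the spread because 2 libraries per group leave too few degrees of freedom alone (4 residual, 3.47 prior). Genes with at least 1 FPKM in at least 2 libraries were tested, 12315 in all. P-values are two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 3 main comparisons were TGF-β with control, TGF-β with MetR against TGF-β, and TGF-β with siHoxc8 against TGF-β, and the other 3 set both combined treatments against control and against each other.

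A total of 28 gene lists were fixed before the data were examined, together with the tests, the alternatives not marked as added later, and the rule for named genes. The 25 lists with at least 5 tested members were tested with camera of limma, which compares a list with all other genes, at its preset correlation of 0.01, with adjustment over the 25 lists of a comparison. Each was tested also with a correlation estimated from the residuals and with fry, which asks whether the genes of a list move on balance in one direction. No list passed camera with the estimated correlation, which rests on 4 residual degrees of freedom, in any of the 6 comparisons, and the numbers at an unadjusted p under 0.05 were 6, 1, 5, 2, 2 and 2 of 25, while fry called 89 of 150 list tests. A few lists use names for which the table holds a synonym, such as Rps19l2 for Rps19.

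Named genes were chosen by a fixed rule. It takes a fixed set of genes whatever their result (Hoxc8, Smad3, Cdk9, Ccnt1, Tgfb1, Acta2, Col1a1, Col3a1 and Fn1), the 8 largest rises and the 8 largest falls of each main comparison among called genes with at least 5 FPKM in the higher group, groups that do not overlap and a symbol without a listed placeholder prefix, and up to 4 members of each list described, by size of change. The prefixes listed were LOC, RGD, AABR, AC0, ENSRNOG, MGC, Olr and Vom, so placeholders with other prefixes passed. For the other comparisons the rule takes 3 rises and 3 falls, and for overlaps the 5 genes with the largest smaller change. Exceptions are named where they occur, and a few genes that the rule takes are not reported here.

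Overlaps of calls between comparisons that share libraries were set beside the number for independent lists, which takes no account of the sharing, and beside 100 simulations of unchanged groups, as were correlations of changes. Each test was first run on simulated data with 200 of 12315 genes changed. At a true fold of 2, limma recovered 56.7% of changed genes for TGF-β against control, 79.1% for MetR against TGF-β and 70.1% for siHoxc8 against TGF-β, and at a fold of 4 it recovered 84.8%, 90.9% and 95.5%. False calls made up 6%, 4.3% and 5.3% of the simulated calls. Recovery was read from 67 changed genes per comparison at a fold of 2 and 66 at a fold of 4. Differences in recovery between the comparisons were not tested. In the deposited data 4792, 6634 and 5394 genes were called, and the SD between replicates ran from 0.177 to 0.307 over the groups. Whether the simulated rates hold for such data was not tested.

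The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median ratio rescaling, quantile normalization, rescaling to TPM, only the libraries of the groups compared, variances without a trend, a minimum of 2-fold, a replicate block, and leaving out each library in turn. Added after seeing the data were limma-voom on the recovered reads, library weights, and removal of each library's trend with gene length. The range of adjusted p given for a gene list covers the alternatives tested with camera at its preset correlation, and leaves out fry and the estimated correlation, and that of a named gene leaves out the minimum of 2-fold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The 20 chromatin samples were not analysed here, as the question followed was gene expression. Col1a2, Col6a3, Gapdh, Cth, E2f1 and Pecam1, members of the lists fixed, were not analysed here.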

Results

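Gene expression was measured by RNA-seq in NRK-49F cells, a fibroblast line from rat kidney, in 4 groups of 2 libraries each. The groups were untreated control cells, cells given transforming growth factor β1 (TGF-β) for 48 h, cells given TGF-β in medium with methionine restriction (MetR), and cells given TGF-β together with a small interfering RNA against the homeobox gene Hoxc8 (siHoxc8). The MetR medium held methionine at 30 uM in place of 200 uM. The reads recovered from the values numbered 17913665 and 17732958 for control, 16199698 and 16380673 for TGF-β, 20146870 and 17466327 for TGF-β with MetR, and 15118113 and 18147345 for TGF-β with siHoxc8. Expression is given as mean FPKM ± SD (n = 2 libraries), and changes as log2 fold changes ± SE of log2(FPKM + 1) from limma, a scale that understates the change of genes with low values. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. The other 20 samples of the series, chromatin immunoprecipitations and their inputs, were not analysed here.

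Hoxc8, a homeobox transcription factor and the target of the siRNA, stood at 1.12 and 1.34 FPKM in the control libraries, 4.32 and 5.01 with TGF-β, 0.417 and 0.614 with TGF-β and MetR, and 0.463 and 0.0771 with TGF-β and siHoxc8. It rose with TGF-β over control by 1.34 ± 0.19 (adjusted p = 0.00171). Against TGF-β alone it was lower with siHoxc8 (log2 fold change -2.17 ± 0.19, adjusted p = 0.000182) and with MetR (-1.90 ± 0.19, adjusted p = 0.000272). Hoxc8 lies in a cluster of overlapping transcripts, and the sources used here do not say whether reads were counted by strand, so reads of a neighbour could not be told from its own.

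**Figure D1:**
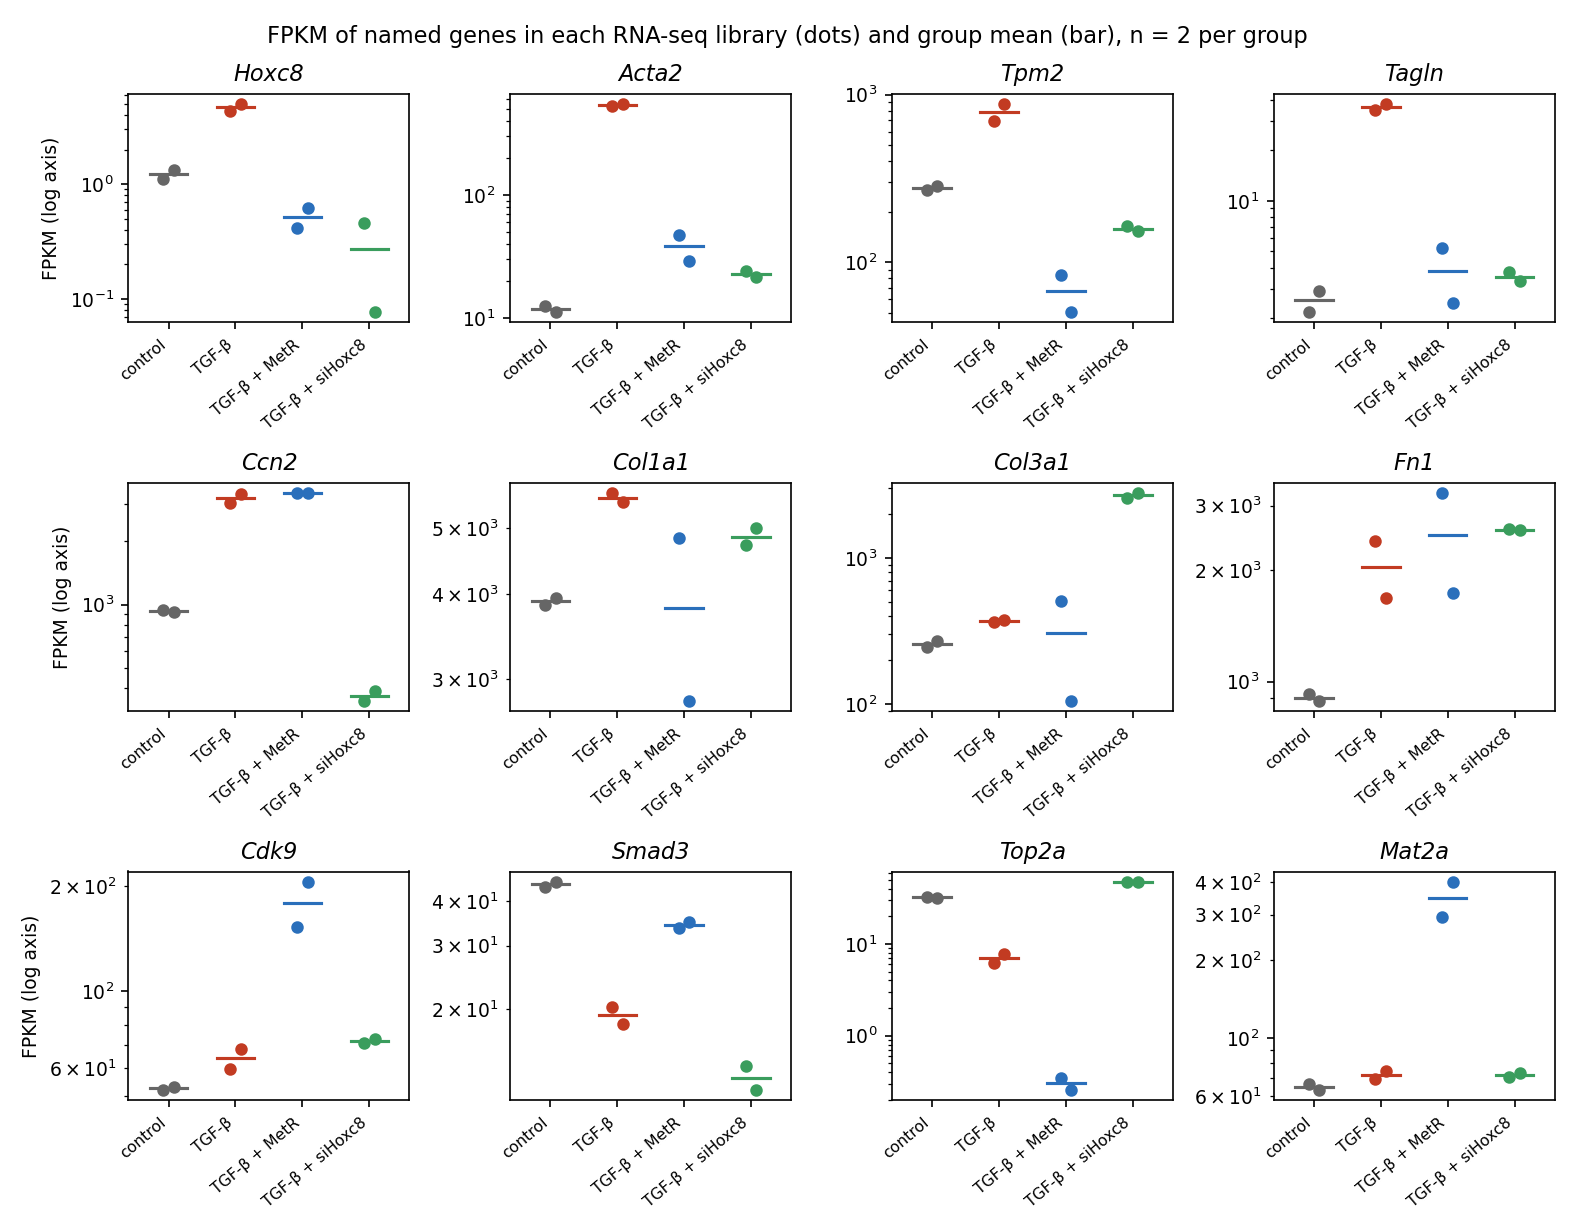
FPKM of 12 named genes in each RNA-seq library (dots, log axis) with the group mean (bar), 2 libraries per group. Hoxc8, Acta2, Tpm2 and Tagln had both TGF-β libraries above all other libraries, and the MetR libraries lay apart from each other for Col1a1, Col3a1 and Fn1.

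The comparison of TGF-β with control asks which genes the cytokine changes as fibroblasts take on the myofibroblast state of kidney fibrosis. Acta2, the smooth muscle actin that marks myofibroblasts, rose from 11.9 ± 0.855 to 539 ± 16.5 FPKM (SD, n = 2 each, 45.4-fold). Other large rises were those of Enpp1 (4.43 ± 0.09), Postn (4.22 ± 0.21), Gadd45g (3.97 ± 0.12), Il1rl1 (3.56 ± 0.23), Tagln (3.40 ± 0.26) and Arl4a (3.27 ± 0.14). Among these, Postn encodes the matrix protein periostin, Gadd45g a growth arrest protein, Il1rl1 the receptor of interleukin 33 and Tagln the actin-binding protein transgelin. The largest falls were those of Aldh3a1, an aldehyde dehydrogenase that went from 815 ± 10.2 to 25.3 ± 0.175 FPKM (n = 2 each), of Selenop (-4.95 ± 0.31), Scara5 (-4.93 ± 0.30), Ccn3 (-4.74 ± 0.28) and Mnda (-4.52 ± 0.14), and of Deptor (-4.17 ± 0.30), Aox1 (-3.98 ± 0.18) and Ptgfr (-3.98 ± 0.20). Selenop encodes a selenium carrier of plasma, Scara5 a ferritin receptor, Deptor an inhibitor of mTOR and Ptgfr the prostaglandin F receptor.

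Genes of the TGF-β response and of contraction rose together. Of 24 tested early TGF-β targets and feedback genes, 16 rose and 8 did not pass the test (16 rose adjusted over the list alone). Their median was 0.92 (camera adjusted p = 3.76e-12, and adjusted p = 0.074 with an estimated correlation). They included Pmepa1 (3.03 ± 0.11), Ccn1 (2.69 ± 0.18) and Ccn2 (1.77 ± 0.11). Pmepa1 is a feedback inhibitor of the pathway, and Ccn1 and Ccn2 are matricellular proteins. Among 20 genes of the contractile apparatus of myofibroblasts, 16 rose and 1 fell (16 and 2 adjusted over the list alone). The list had a median of 0.82 (camera adjusted p = 2.29e-12, and adjusted p = 0.0913 with an estimated correlation). Cald1, which binds actin and tropomyosin, rose by 2.22 ± 0.13 and Pdlim7, a protein of actin filaments, by 1.61 ± 0.10. The ligands, receptors and Smads of the pathway moved both ways, with 5 of 17 raised and 6 lowered (5 and 7 adjusted over the list alone). Their median was -0.21 while their mean lay 0.05 above other genes, the camera test pointed up without passing (adjusted p = 0.653), and the median was 0.01 after median ratio rescaling. Tgfb1 and Tgfb2, genes of the ligands, rose by 1.15 ± 0.09 and 1.39 ± 0.28, whereas the receptor genes Tgfbr2 and Tgfbr3 fell (-1.40 and -2.04) and Smad3, which carries the signal to the nucleus, fell from 44.5 ± 0.964 to 19.2 ± 1.52 FPKM (-1.17 ± 0.11, adjusted p = 0.000292).

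Matrix genes did not move as 1 group. Of 26 matrix glycoproteins and proteoglycans, 10 rose and 3 fell (10 and 3 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.000428, and adjusted p = 0.689 with an estimated correlation, median 0.41 to 0.67 over the scalings tried). Fbln2 (from 60.2 ± 2.62 to 302 ± 19.4 FPKM), Tnc (1.86 ± 0.22) and Tgfbi (1.72 ± 0.29) were among the risers. Of 19 genes that modify and crosslink collagen, 7 rose and 1 fell (7 and 1 adjusted over the list alone). The genes had a median of 0.24 (camera adjusted p = 0.00561, and adjusted p = 0.723 with an estimated correlation, median 0.17 to 0.47 over the scalings tried), led by Plod2 (1.24 ± 0.18), Lox (1.17 ± 0.22) and Plod3 (0.88 ± 0.09). Both of these calls ended under quantile normalization, and over the alternatives tried their adjusted p ran from 3.86e-05 to 0.198 and from 0.00437 to 0.349. Of 17 collagen genes 4 were called raised, 4 lowered and 9 neither (4 and 4 adjusted over the list alone, camera adjusted p = 0.113). Their median was 0.51 (0.33 to 0.81 over the scalings tried), while their mean lay only 0.08 above other genes. Col4a1, of basement membranes, rose by 1.95 ± 0.18 and Col14a1 (-3.66 ± 0.33), Col6a1 (-2.68 ± 0.27) and Col18a1 (-2.52 ± 0.14) fell. Col1a1, the main chain of type I collagen, stood at 3900.0 ± 69 FPKM in control and 5538 ± 126 with TGF-β (0.51 ± 0.24, adjusted p = 0.131), and Col3a1 at 258 ± 15.6 and 370.5 ± 4.65 (0.52 ± 0.59, adjusted p = 0.518). Among other alternatives, both passed once MetR replicate 1 or 2 was left out of the shared estimate of spread (Col1a1 adjusted p = 0.0207 and 0.0221, range 0.0207 to 0.606 over the alternatives, and Col3a1 adjusted p = 0.00346 and 0.00396, range 0.00346 to 0.711). Fn1, fibronectin, rose from 905 ± 26.2 to 2049 ± 512 FPKM (1.16 ± 0.29, adjusted p = 0.0171), a call lost with no filter on low values and without control replicate 1, control replicate 2 or TGF-β replicate 1 (adjusted p = 0.0683, 0.0805, 0.0879 and 0.0955, range 0.00161 to 0.0955 over the alternatives).

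Proliferation and interferon genes were lower with TGF-β. Of 38 tested cell cycle genes, 36 fell and 2 did not pass (36 fell adjusted over the list alone). The median change was -1.31 (camera adjusted p = 1.23e-12, and adjusted p = 0.196 with an estimated correlation). Top2a, the topoisomerase of dividing cells, went from 32.4 ± 0.796 to 7.01 ± 1.17 FPKM (-2.07 ± 0.13), and Mki67 (-1.94 ± 0.12) and Foxm1 (-1.68 ± 0.11) fell with it. In the interferon response list 18 of 23 genes fell and 1 rose (the same numbers adjusted over the list alone). These genes had a median of -0.97 (camera adjusted p = 3.15e-05, and adjusted p = 0.149 with an estimated correlation, median -1.09 to -0.64 over the scalings tried), for example Ifit2 (-2.04 ± 0.12), Gbp2 (-1.99 ± 0.11) and Bst2 (-1.92 ± 0.17). Glycolysis and hypoxia genes rose in 9 and fell in 3 of 23 cases (11 and 3 adjusted over the list alone). Their median change was 0.37 (camera adjusted p = 7e-05, and adjusted p = 0.188 with an estimated correlation, median 0.36 to 0.58 over the scalings tried). Ldha, lactate dehydrogenase, rose by 1.24 ± 0.11 and Slc2a1, a glucose transporter, by 1.11 ± 0.19, while Adm, adrenomedullin, fell by 2.15 ± 0.15.

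Hox genes, which set positional identity, rose in 11 and fell in 2 of 22 cases (12 and 2 adjusted over the list alone). Their median was 0.51 (camera adjusted p = 7.19e-06, and adjusted p = 0.148 with an estimated correlation), among them Hoxb9 (1.55 ± 0.11), Hoxc9 (1.51 ± 0.22) and Hoxd13 (1.05 ± 0.12). P-TEFb, the kinase that releases paused RNA polymerase II, is made of Cdk9 and a cyclin T. Cdk9 stood at 52.6 ± 0.803 FPKM in control and 64.1 ± 5.87 with TGF-β (0.28 ± 0.14, adjusted p = 0.167). The change passed with library weights, with the length trend removed, after median ratio rescaling and without MetR replicate 1 or 2 (adjusted p = 0.0451, 0.0207, 0.0209, 0.0263 and 0.0264, range 0.0207 to 0.474 over the alternatives). Ccnt1, the gene of cyclin T1, stood at 1.2 ± 0.108 and 1.46 ± 0.338 FPKM (0.16 ± 0.23, adjusted p = 0.603). Of 31 P-TEFb and pause release genes, 1 rose and 8 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.877). The median of that list was -0.17 as deposited and 0.04 after median ratio rescaling, and its mean lay 0.03 above other genes while the test pointed down, with Ccnt2 (-0.92) and Nelfcd (-0.83) among those that fell.

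In all, limma called 1269 of 12315 tested genes raised and 3523 lowered by TGF-β, of which 345 and 945 differed at least 2-fold. Both libraries of one group lay beyond both of the other for 75.7% of genes, where chance alone gives 33.3%. The 33.3% assumes no shift of whole libraries, and the share was not computed again after rescaling. In this comparison 13 of 25 gene lists passed the camera test with its preset correlation. The balance of raised and lowered genes rested on the scaling of the libraries, since the median of all genes was -0.19 as deposited and median ratio rescaling moved it by 0.19 and gave 2274 raised and 2140 lowered genes, with 2079 and 2102 after quantile normalization. The counts fell to 620 and 1700 without control replicate 1 and to 649 and 1823 without control replicate 2.

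The comparison of MetR with TGF-β alone asks what a low methionine supply changes in cells under the cytokine. Acta2 fell from 539 ± 16.5 to 38.2 ± 12.8 FPKM (SD, n = 2 each, 14.1-fold lower), and Tpm2, a tropomyosin of actin filaments, from 786 ± 132 to 67.1 ± 23.4. The other large falls were those of Akap5 (-4.54 ± 0.24), Tm7sf2 (-4.08 ± 0.14) and Angptl2 (-4.01 ± 0.32) and of Fam25a (-3.42 ± 0.26), Odf3l1 (-3.38 ± 0.18) and Kazald1 (-3.17 ± 0.20), where Akap5 anchors protein kinase A and Tm7sf2 is a sterol reductase of cholesterol synthesis. Cyp3a9, a cytochrome P450, rose from 0.121 ± 0.0564 to 41.7 ± 9 FPKM (n = 2 each), followed by Fmr1nb (4.39 ± 0.11), AC115401.1 (4.36 ± 0.50) and Rrad (3.81 ± 0.16) and Ppef1 (3.62 ± 0.27), Egr1 (3.56 ± 0.32), Lum (3.48 ± 0.61) and Tfec (3.37 ± 0.14). Rrad is a small GTPase, Egr1 an immediate early transcription factor and Lum the proteoglycan lumican. Mat2a, which makes S-adenosylmethionine from methionine, rose from 72.2 ± 3.4 to 347 ± 76.7 FPKM (2.23 ± 0.14, adjusted p = 7.03e-05).

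Contractile genes were lower with MetR, as 13 of 20 fell and 2 rose (the same numbers adjusted over the list alone). The list had a median of -0.89 (camera adjusted p = 9.12e-06, and adjusted p = 0.456 with an estimated correlation). Tagln fell from 36.1 ± 2.31 to 3.84 ± 1.95 FPKM, and Cald1 fell by 1.98 ± 0.13. Early TGF-β targets went both ways, with 6 of 24 raised and 6 lowered (the same numbers adjusted over the list alone, camera adjusted p = 0.461), and the median was 0.16 as deposited and -0.05 after median ratio rescaling while the mean lay below other genes (-0.22). Il11, an interleukin, fell by 1.86 ± 0.18, whereas Junb, a subunit of the AP-1 transcription factor, rose by 2.66 ± 0.29. Of 17 ligand, receptor and Smad genes 7 rose and 4 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.914), with Tgfb2 at -2.71 ± 0.28, Tgfb3 at -1.05 ± 0.13 and Tgfb1 at -0.56 ± 0.09 (adjusted p = 0.00187). Smad3 rose from 19.2 ± 1.52 to 34.2 ± 0.897 FPKM (0.80 ± 0.11, adjusted p = 0.000848), still below its control level.

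The MetR libraries differed from each other for matrix genes, which stood higher in replicate 1 for 41 of 43 collagen and matrix glycoprotein genes. Col3a1 stood at 506 FPKM in MetR replicate 1 and 105 in replicate 2, on either side of 370.5 ± 4.65 with TGF-β alone (log2 fold change -0.68 ± 0.59, adjusted p = 0.363). Without replicate 1 its change was -1.81 (adjusted p = 7.59e-05) and without replicate 2 it was 0.45 (adjusted p = 0.0141), with a range of 7.59e-05 to 0.654 over the alternatives. Col1a1 stood at 4837 and 2788 FPKM with MetR against 5538 ± 126 with TGF-β alone (-0.59 ± 0.24, adjusted p = 0.0693). Its fall passed with all libraries kept after median ratio rescaling, with limma-voom and with the length trend removed, and without MetR replicate 1 (adjusted p = 0.0318, 0.0403, 0.0111 and 0.0026, range 0.0026 to 0.359). Fn1 stood at 3246 and 1737 FPKM (0.23 ± 0.29, adjusted p = 0.517) and passed without MetR replicate 2 (adjusted p = 0.0385, range 0.0385 to 0.965). Of 17 collagen genes 6 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.209), with Col8a1 at -2.71 ± 0.34, Col4a1 at -1.64 ± 0.18 and Col11a1 at 2.21 ± 0.48. The collagen median was -0.38 (-0.66 to -0.04 over the scalings tried), with 0.40 in MetR replicate 1 and -0.52 in replicate 2. The list passed at a mean FPKM of at least 5 and without MetR replicate 1 (adjusted p = 0.0322 and 0.018, range 0.018 to 0.943). Matrix glycoproteins rose in 6 and fell in 8 of 26 cases (the same numbers adjusted over the list alone, camera adjusted p = 0.247, and 0.00727 without MetR replicate 1, range 0.00727 to 0.904), with Sparc at -2.34 ± 0.49 and Postn at 1.71 ± 0.21. Genes that modify and crosslink collagen fell in 12 and rose in 1 of 19 cases (the same numbers adjusted over the list alone). The median was -0.75 (camera adjusted p = 0.000179, and adjusted p = 0.55 with an estimated correlation), led by the lysyl oxidase genes Loxl1 (-2.96 ± 0.21), Lox (-1.77 ± 0.22) and Loxl2 (-1.22 ± 0.21). All 19 stood higher in MetR replicate 1, and the median change was -0.38 in that library and -0.99 in replicate 2.

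Ribosomal protein genes had the smallest camera p of this comparison. Of 52 tested, 46 fell and 6 did not pass (46 fell adjusted over the list alone). The genes had a median of -1.26 (camera adjusted p = 4.39e-22, and adjusted p = 0.456 with an estimated correlation), for example Rps27 (-2.08 ± 0.15), Rpl24 (-1.94 ± 0.20) and Rps21 (-1.94 ± 0.19). These genes have many near-identical copies in the genome, so the split of reads among them is uncertain. Of 31 genes of cholesterol and fatty acid synthesis 27 fell and 4 did not pass (27 fell adjusted over the list alone). The median change was -1.09 (camera adjusted p = 1.62e-13, and adjusted p = 0.456 with an estimated correlation). Scd, the fatty acid desaturase, fell by 2.66 ± 0.16, Acat2 by 2.24 ± 0.21 and Hmgcs1, an early enzyme of the sterol pathway, by 1.92 ± 0.15. Cell cycle genes fell below their level with TGF-β alone in 24 of 38 cases and rose in 2 (the same numbers adjusted over the list alone). These genes had a median of -0.67 (camera adjusted p = 3.05e-09, and adjusted p = 0.456 with an estimated correlation). Top2a went from 7.01 ± 1.17 to 0.301 ± 0.0637 FPKM, Birc5 and Ccnb1 changed by -2.12 and -1.73, and Mcm7, part of the replicative helicase, rose by 1.85 ± 0.19.

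Genes of the amino acid response driven by ATF4 were higher with MetR, with 22 of 33 raised and 3 lowered (24 and 3 adjusted over the list alone) and a median of 1.00 (camera adjusted p = 0.000692, and adjusted p = 0.549 with an estimated correlation). Stc2, a secreted glycoprotein, rose by 3.05 ± 0.20, the amino acid transporter gene Slc7a5 by 2.55 ± 0.17 and Trib3, a pseudokinase, by 2.33 ± 0.19. Cytosolic aminoacyl-tRNA synthetase genes rose in 11 and fell in 2 of 20 cases (the same numbers adjusted over the list alone, camera adjusted p = 0.115, and 0.0441 with no filter on low values, 0.0446 under quantile normalization and 0.00727 without MetR replicate 1, range 0.00727 to 0.436), with Aars at 1.30 ± 0.08. The methionine cycle list itself had 5 of 18 genes raised and 3 lowered (the same numbers adjusted over the list alone, camera adjusted p = 0.876): besides Mat2a, Mtr, methionine synthase, rose by 0.95 ± 0.12 and Ahcyl1 fell by 1.21 ± 0.09. Glycolysis and hypoxia genes fell in 12 and rose in 3 of 23 cases with MetR (the same numbers adjusted over the list alone, camera adjusted p = 0.00233, and adjusted p = 0.456 with an estimated correlation). Endoplasmic reticulum chaperone genes fell in 10 and rose in 4 of 20 cases with MetR (11 and 5 adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.55 with an estimated correlation). The chaperone call was lost under quantile normalization and without MetR replicate 1 (adjusted p = 0.153 and 0.0572, range 0.00376 to 0.153).

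Genes of the enzymes that write and erase methylation of histone H3 at K4 and K36, whose writers use S-adenosylmethionine, rose in 20 and fell in 1 of 32 cases (the same numbers adjusted over the list alone). Their median change was 0.50 (camera adjusted p = 0.00432, and adjusted p = 0.456 with an estimated correlation, median 0.22 to 0.61 over the scalings tried), among them Riox1 (1.62 ± 0.16), Setd1b (1.33 ± 0.19) and Kdm4a (1.11 ± 0.11). Part of this rise made up for a fall with TGF-β, which lowered 13 and raised 0 of the 32 (median -0.35, camera adjusted p = 0.135). Relative to the control mean, the median was -0.26 and -0.40 in the TGF-β libraries and 0.25 and 0.24 in the MetR libraries. Cdk9 rose from 64.1 ± 5.87 to 179.7 ± 37.4 FPKM (1.46 ± 0.14, adjusted p = 0.000252). Ccnt1 stood at 1.46 ± 0.338 and 2.16 ± 0.988 FPKM (0.33 ± 0.23, adjusted p = 0.248) and passed without MetR replicate 2 (adjusted p = 0.0208, range 0.0208 to 0.978 over the alternatives). Of 31 P-TEFb and pause release genes 14 rose and 3 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.115, range 0.0443 to 0.339, past the threshold with no filter on low values), including the elongation factor genes Ell (1.12 ± 0.12) and Aff1 (0.94 ± 0.18) and Hexim1, an inhibitor of P-TEFb (0.91). Immediate early genes rose in 13 and fell in 2 of 18 cases (the same numbers adjusted over the list alone). Their median was 0.74 (camera adjusted p = 0.0227, and adjusted p = 0.477 with an estimated correlation), for example Ier2 (3.06 ± 0.36) and Fosl1 (2.44 ± 0.41). That list did not pass at a mean FPKM of at least 5 or without TGF-β replicate 1 (adjusted p = 0.164 and 0.0528, range 0.00437 to 0.164 over the alternatives). Of 15 p53 target and arrest genes 9 rose and 1 fell (10 and 1 adjusted over the list alone). The list had a median of 0.56 (camera adjusted p = 0.0236, and adjusted p = 0.456 with an estimated correlation), among them Gadd45a (2.54 ± 0.27), Plk2 (2.29 ± 0.13) and Mdm2 (1.46 ± 0.13).

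Against TGF-β alone, MetR raised 4289 and lowered 2345 of 12315 genes by limma, 1319 and 826 of them at least 2-fold. The groups did not overlap for 73% of genes, against 33.3% by chance where whole libraries do not shift. With MetR 11 of 25 lists passed camera with its preset correlation. The split was 3165 raised and 3264 lowered after median ratio rescaling, which moved the median of all genes by -0.18, and 3290 and 3072 after quantile normalization. The MetR libraries had the widest spread between replicates, and the shared estimate of spread takes no account of that. With library weights 3068 genes rose and 1616 fell, and with only the libraries of the groups compared 3017 rose and 1657 fell. The labels do not say whether the libraries without restriction were grown in the same base medium, so the change of medium and of methionine could not be separated.

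**Figure D2:**
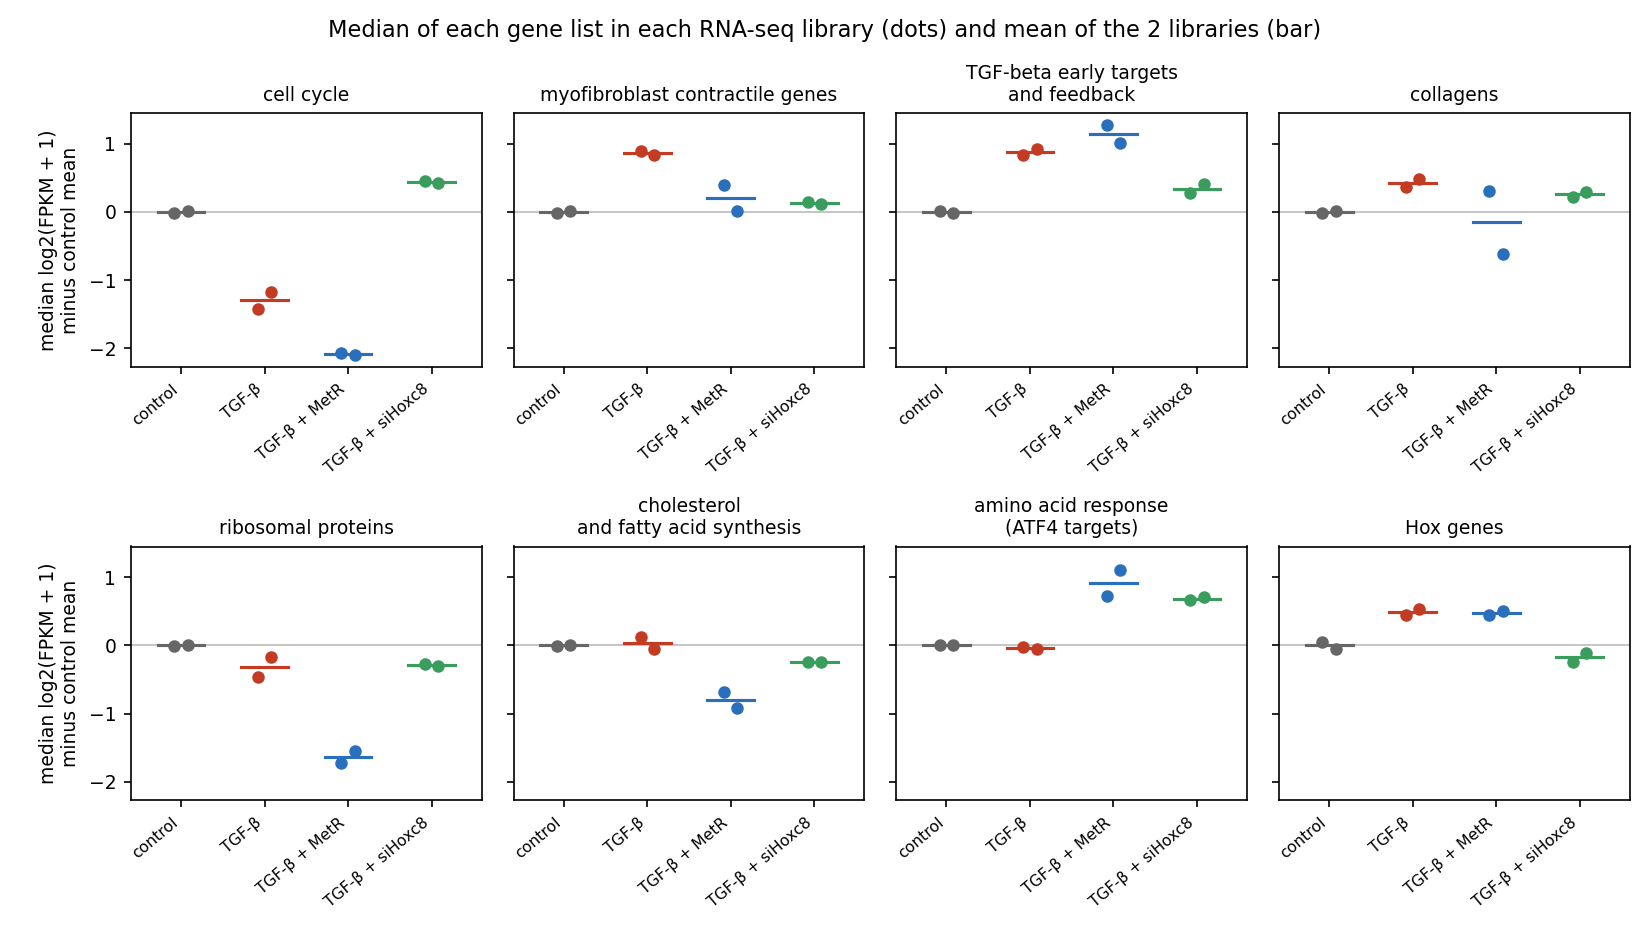
Median of 8 gene lists in each RNA-seq library, as log2(FPKM + 1) minus the control mean (dots), with the mean of the 2 libraries (bar). Cell cycle genes lay lowest with MetR and highest with siHoxc8, and ribosomal protein genes lay lowest with MetR, under each scaling tried.

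The comparison of siHoxc8 with TGF-β alone asks which genes depend on Hoxc8 in cells under the cytokine. Acta2 fell from 539 ± 16.5 to 23 ± 1.92 FPKM (SD, n = 2 each, 23.5-fold lower). F13a1, a subunit of the fibrin-crosslinking factor XIII, rose from 0.0319 ± 0.000251 to 241 ± 7.22 FPKM, and Mmp3, a matrix metalloprotease, from 2.12 ± 0.237 to 91.7 ± 2.56. Fmr1nb (5.93 ± 0.11), Mmp13 (4.63 ± 0.59), Slc25a48 (4.18 ± 0.18) and Lamb3 (3.94 ± 0.29) and Ca3 (3.91 ± 0.46) and Slc17a6 (3.86 ± 0.36) also rose, where Mmp13 is a collagenase, Lamb3 a laminin chain and Ca3 a carbonic anhydrase. Other large falls were those of Akap5 (-4.71 ± 0.24), Vgll3 (-4.17 ± 0.15) and Ccdc9b (-4.11 ± 0.36) and of Trpc6 (-3.96 ± 0.20), Anxa8 (-3.94 ± 0.37) and Ca9 (-3.88 ± 0.51). Vgll3 is a cofactor of TEAD transcription factors, Trpc6 a cation channel and Ca9 a carbonic anhydrase of the hypoxia response. Mir145, a microRNA gene of contractile cells, stood at 9.81 and 18 FPKM with TGF-β and was listed at 0 in both siHoxc8 libraries.

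Contractile genes and TGF-β targets were lower with siHoxc8. Of 20 contractile genes 15 fell and 2 rose (16 and 2 adjusted over the list alone). The median was -0.99 (camera adjusted p = 5.85e-08, and adjusted p = 0.18 with an estimated correlation), among them Itga11 (-3.29 ± 0.36), Tagln (-3.03 ± 0.26) and Tpm2 (-2.29 ± 0.22). Early TGF-β targets fell in 11 and rose in 4 of 24 cases (the same numbers adjusted over the list alone). The genes had a median of -0.21 (camera adjusted p = 0.000341, and adjusted p = 0.18 with an estimated correlation, median -0.37 to -0.21 over the scalings tried). Ccn2 fell from 3200.0 ± 200.3 to 368 ± 27.6 FPKM (-3.12 ± 0.11), and Ccn1 (-2.68 ± 0.18) and Tgfb1i1 (-2.67 ± 0.09) fell with it. Smad3 fell from 19.2 ± 1.52 to 12.9 ± 1.38 FPKM (-0.55 ± 0.11, adjusted p = 0.00561), a call lost without siHoxc8 replicate 2 (adjusted p = 0.0563, range 0.00111 to 0.0563 over the alternatives). Of 17 ligand, receptor and Smad genes 5 rose and 2 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.876), with Tgfb2 at -2.19 ± 0.28 and Tgfbr3 at 1.29 ± 0.16, while Tgfb1 stood at 79.6 ± 0.482 FPKM (0.14 ± 0.09, adjusted p = 0.247).

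Matrix genes again went both ways. Col3a1 rose from 370.5 ± 4.65 to 2687 ± 139.5 FPKM (2.85 ± 0.59, adjusted p = 0.00676), and the type VI collagen genes Col6a1 (2.44 ± 0.27) and Col6a2 (1.97 ± 0.23) rose, whereas Col4a1 fell by 2.01 ± 0.18. Col1a1 stood at 4854 ± 194 FPKM (-0.19 ± 0.24, adjusted p = 0.548) and Fn1 at 2583 ± 2.59 (0.36 ± 0.29, adjusted p = 0.349). Over all 17 collagen genes 4 rose and 2 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.83), with a median of -0.14 that was 0.22 after quantile normalization and a mean 0.06 above other genes although the test pointed down. Matrix glycoproteins fell in 11 and rose in 5 of 26 cases (the same numbers adjusted over the list alone). The median change was -0.22 (camera adjusted p = 0.0457, and adjusted p = 0.862 with an estimated correlation, median -0.39 to -0.22 over the scalings tried). Nid1 (-2.71 ± 0.13) and Thbs1 (-2.47 ± 0.20) fell, while Tgfbi rose from 229 ± 17.9 to 919 ± 14.6 FPKM. The call of the list was lost under most alternatives, without TGF-β replicate 1 and without MetR replicate 1 or 2 among them (adjusted p = 0.0809, 0.12 and 0.123, range 0.0193 to 0.317). Genes that modify and crosslink collagen fell in 9 and rose in 3 of 19 cases (9 and 4 adjusted over the list alone). These genes had a median of -0.12 (camera adjusted p = 0.0231, and adjusted p = 0.847 with an estimated correlation, median -0.29 to -0.12 over the scalings tried), led by P4ha2 (-1.35 ± 0.14) and Lox (-1.23 ± 0.22). This call did not pass under quantile normalization (range of adjusted p 0.0111 to 0.132). Matrix proteases and their inhibitors rose in 7 and fell in 5 of 17 cases (the same numbers adjusted over the list alone, camera adjusted p = 0.83), with Mmp10 at 3.79 ± 0.38 and Mmp2 at 1.21 ± 0.11.

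Cell cycle genes rose with siHoxc8 in 37 of 38 cases and 1 did not pass (37 rose adjusted over the list alone). Their median change was 1.79 (camera adjusted p = 1.73e-16, and adjusted p = 0.214 with an estimated correlation). Top2a went from 7.01 ± 1.17 to 47.6 ± 0.0932 FPKM, and Mcm5 (2.90 ± 0.16), Ccnb1 (2.69 ± 0.20) and Ube2c (2.41 ± 0.15) rose with it. Of 15 p53 target and arrest genes 8 fell and 3 rose (the same numbers adjusted over the list alone). Their median was -0.40 (camera adjusted p = 0.00373, and adjusted p = 0.18 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases, fell by 1.64 ± 0.10 and Cdkn2c, another, rose by 1.74 ± 0.17. ATF4 targets rose in 26 and fell in 1 of 33 cases (27 and 1 adjusted over the list alone). The list had a median of 0.71 (camera adjusted p = 1.89e-05, and adjusted p = 0.506 with an estimated correlation), for example Slc7a5 (2.66 ± 0.17), Aldh1l2 (1.82 ± 0.28) and Psph (1.46 ± 0.19). Of 20 aminoacyl-tRNA synthetase genes 15 rose and 5 did not pass (17 raised and 1 lowered adjusted over the list alone). The median was 0.54 (camera adjusted p = 0.000696, and adjusted p = 0.639 with an estimated correlation), led by Aars (1.13 ± 0.08) and by Yars1 (from 61.6 ± 2.56 to 130.0 ± 7 FPKM). Endoplasmic reticulum chaperone genes rose in 11 and fell in 1 of 20 cases (the same numbers adjusted over the list alone). The genes had a median of 0.44 (camera adjusted p = 0.0226, and adjusted p = 0.639 with an estimated correlation, median 0.28 to 0.44 over the scalings tried), among them Creld2 (1.51 ± 0.13), Hsp90b1 (1.25 ± 0.13) and Calr (0.96 ± 0.11).

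Cholesterol and fatty acid genes fell in 13 and rose in 1 of 31 cases with siHoxc8 (14 and 1 adjusted over the list alone). The median change was -0.38 (camera adjusted p = 5.83e-05, and adjusted p = 0.639 with an estimated correlation), such as Tm7sf2 (-1.54 ± 0.14) and Hmgcs1 (-0.98 ± 0.15). Glycolysis and hypoxia genes fell in 11 and rose in 3 of 23 cases (the same numbers adjusted over the list alone). These genes had a median of -0.24 (camera adjusted p = 0.00171, and adjusted p = 0.39 with an estimated correlation, median -0.41 to -0.24 over the scalings tried), such as Mxi1 (-1.62 ± 0.11) and Ankrd37 (-1.28 ± 0.19). Hox genes fell in 11 and rose in 1 of 22 cases (the same numbers adjusted over the list alone). Their median change was -0.46 (camera adjusted p = 0.000146, and adjusted p = 0.18 with an estimated correlation), and Hoxc6 (-1.52 ± 0.11) and Hoxc9 (-1.33 ± 0.22) fell beside Hoxc8. Of 31 P-TEFb and pause release genes 10 rose and 7 fell (13 and 7 adjusted over the list alone, camera adjusted p = 0.962, median 0.02 to 0.17 over the scalings tried), with a median of 0.17 and a mean below other genes (-0.03) although the test pointed up. Ell2, an elongation factor gene, fell by 1.22 ± 0.14 and Nelfa, of the pausing complex, rose by 1.00 ± 0.11. Cdk9 stood at 71.7 ± 1.39 FPKM (0.16 ± 0.14, adjusted p = 0.39). Ccnt1 stood at 2.74 ± 0.117 FPKM (0.61 ± 0.23, adjusted p = 0.0617) and passed with library weights, with only the libraries of the groups compared and without MetR replicate 1 or 2 (adjusted p = 0.0213, 0.0252, 0.0127 and 0.0122, range 0.0122 to 0.248 over the alternatives).

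With siHoxc8, limma called 3460 genes raised and 1934 lowered of 12315 against TGF-β alone, 962 and 582 of them at least 2-fold. The groups did not overlap for 76.8% of genes, against 33.3% by chance where whole libraries do not shift. With siHoxc8 12 of 25 lists passed camera with its preset correlation. The split was 2591 and 2718 after median ratio rescaling, which moved the median of all genes by -0.14, and 2723 and 2677 after quantile normalization. The counts fell to 2004 and 1148 without siHoxc8 replicate 1 and to 2120 and 1247 without siHoxc8 replicate 2. The RNA-seq groups hold no library of TGF-β with a control siRNA, so effects of transfection could not be separated from those of Hoxc8.

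**Figure D3:**
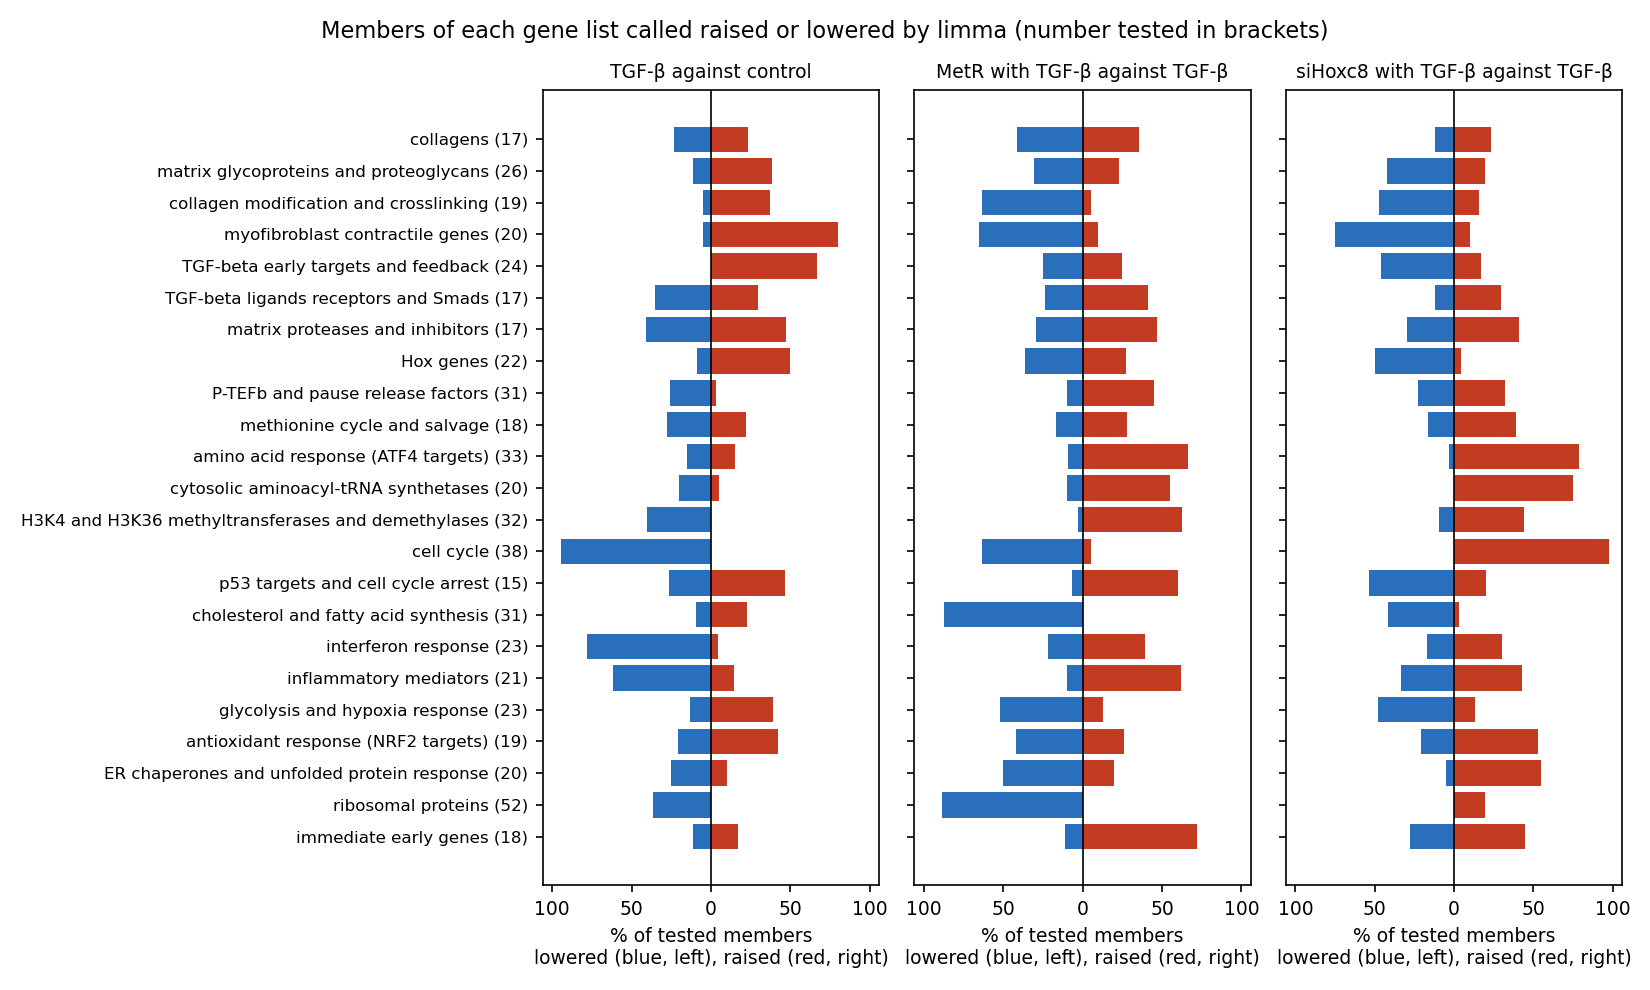
Percent of the tested members of each gene list that limma called raised (red, right) or lowered (blue, left) in the comparisons of TGF-β with control, MetR with TGF-β and siHoxc8 with TGF-β. Cell cycle genes were lowered in 36, lowered in 24 and raised in 37 of 38 cases.

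Set against control, TGF-β with MetR raised early TGF-β targets and lowered cell cycle and ribosomal protein genes. Gadd45g, a growth arrest gene, rose from 22.2 ± 1.59 to 2121 ± 30.1 FPKM (SD, n = 2 each), and Postn (5.93 ± 0.21) and Rrad (5.17 ± 0.16) rose as well, while Ccn3 (-5.69 ± 0.28), Aox1 (-5.08 ± 0.18) and Aldh3a1 (-5.08 ± 0.28) fell. Early TGF-β targets rose in 16 and fell in 5 of 24 cases over control (the same numbers adjusted over the list alone). Their median was 1.07 (camera adjusted p = 0.000543, and adjusted p = 0.363 with an estimated correlation). Cell cycle genes fell in 35 of 38 cases and 3 did not pass (35 fell adjusted over the list alone). The list had a median of -2.09 (camera adjusted p = 2.1e-14, and adjusted p = 0.363 with an estimated correlation). Ribosomal protein genes fell in 50 of 52 cases (51 adjusted over the list alone). The median was -1.68 (camera adjusted p = 8.08e-17, and adjusted p = 0.464 with an estimated correlation), and ATF4 targets rose in 25 and fell in 4 of 33 (25 and 4 adjusted over the list alone, camera adjusted p = 2.32e-05, and adjusted p = 0.464 with an estimated correlation). In this comparison 3452 genes were called raised and 3607 lowered.

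Set against control, TGF-β with siHoxc8 raised F13a1 from 0.00726 ± 0.0103 to 241 ± 7.22 FPKM (SD, n = 2 each) and Postn by 5.72 ± 0.21, and lowered Ccn3 (-6.83 ± 0.28), Aldh3a1 (-6.13 ± 0.28) and Scara5 (-5.97 ± 0.30). Fmr1nb was listed at 0 in both control libraries and stood at 65.3 and 62.7 FPKM with siHoxc8. ATF4 targets rose in 24 and fell in 1 of 33 cases over control (25 and 1 adjusted over the list alone). The genes had a median of 0.71 (camera adjusted p = 2.36e-06, and adjusted p = 0.676 with an estimated correlation). Cell cycle genes stood above control in 19 of 38 cases and below in 3 (23 and 3 adjusted over the list alone). The median change was 0.45 (camera adjusted p = 5.14e-05, and adjusted p = 0.777 with an estimated correlation). Interferon response genes fell in 15 and rose in 1 of 23 cases (15 and 1 adjusted over the list alone). These genes had a median of -0.72 (camera adjusted p = 0.000211, and adjusted p = 0.424 with an estimated correlation). Contractile genes had 6 raised and 8 lowered of 20 (6 and 8 adjusted over the list alone, camera adjusted p = 0.705). The totals were 2668 raised and 3331 lowered genes, and 1687 and 2156 without control replicate 1, 1682 and 2211 without control replicate 2, 1676 and 2217 without siHoxc8 replicate 1, and 1709 and 2273 without siHoxc8 replicate 2.

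Compared directly, siHoxc8 and MetR differed in proliferation and ribosomal genes. Cell cycle genes stood higher with siHoxc8 in 34 of 38 cases (35 adjusted over the list alone), with a median difference of 2.61 (camera adjusted p = 7.5e-20, and adjusted p = 0.404 with an estimated correlation), and Top2a differed by 5.22 ± 0.13. Ribosomal protein genes were higher in 51 of 52 cases (51 adjusted over the list alone), with a median difference of 1.42 (camera adjusted p = 1.02e-18, and adjusted p = 0.522 with an estimated correlation), and cholesterol and fatty acid genes in 23 of 31, with 1 lower (23 and 1 adjusted over the list alone, camera adjusted p = 9.77e-07, and adjusted p = 0.535 with an estimated correlation). Early TGF-β targets were lower with siHoxc8 in 14 and higher in 3 of 24 cases (14 and 4 adjusted over the list alone), with a median difference of -0.74 (camera adjusted p = 0.02, and adjusted p = 0.443 with an estimated correlation). F13a1 and Igfbp5, a binding protein of insulin-like growth factors, were higher with siHoxc8 by 6.25 ± 0.12 and 4.53 ± 0.43, and Gadd45g (-5.74 ± 0.12), Hrct1 (-4.45 ± 0.25) and Vgll3 (-4.30 ± 0.15) were lower (SE, n = 2 each). A total of 3066 genes were called higher and 3614 lower with siHoxc8, or 3321 and 3400 after median ratio rescaling.

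Overlaps were set beside those of independent lists, although the comparisons share libraries. In 100 simulations of unchanged groups with the same sharing the mean overlap was at most 0.01 genes, as almost nothing is called there, and how much overlap the sharing creates among changed genes was not tested. Genes raised by TGF-β and lowered by MetR numbered 515, where independent lists give 241.6, and led with Acta2, Tagln, Ggt1, Serpini1 and Akap5. Genes lowered by TGF-β and raised by MetR numbered 1386, where independent lists give 1227, among them Serpinb7, Il19, Angpt1 and Mmp3. For siHoxc8, 511 genes were raised by TGF-β and lowered by the siRNA (199.3 for independent lists), among them Acta2, AC130253.2, Gadd45g and Trpc6, and 1382 were lowered by TGF-β and raised by the siRNA (989.8), led by Ptgfr, Dscc1, Angpt1, Il33 and Col6a1. MetR and siHoxc8 both raised 1719 genes (1205 for independent lists), led by Fmr1nb, Cyp3a9, Cxcl13, Tfec and Ptprn, and both lowered 815 (368.3), led by Akap5, Acta2, Mir145, Tagln and Wnt4. These numbers moved with scaling: after median ratio rescaling they were 1038 and 608 for MetR, 977 and 820 for siHoxc8, and 1071 raised and 1311 lowered for both. The numbers of genes called moved too, and those for independent lists were not computed again after rescaling or with a library left out. The overlaps found there can therefore not be set beside the numbers for independent lists given above. Without control replicate 1 the overlaps with the TGF-β calls were 273 and 563 for MetR and 280 and 710 for siHoxc8, and without control replicate 2 they were 295, 594, 292 and 765. The overlaps with MetR were 334 and 817 without TGF-β replicate 2. Without siHoxc8 replicate 1 the overlaps with siHoxc8 were 321 and 828, with 945 genes raised and 531 lowered by both, and without siHoxc8 replicate 2 they were 336 and 847, with 1003 raised by both.

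Across the 12315 tested genes, which are not independent replicates, the TGF-β change correlated with the MetR change at r = -0.18 (Spearman rho = -0.14) and with the siHoxc8 change at r = -0.29 (rho = -0.25), and the MetR change with the siHoxc8 change at r = 0.34 (rho = 0.32). Shared libraries alone gave simulated values of -0.46, -0.60 and 0.45. The covariances were -0.090, -0.133 and 0.189 against simulated covariances of -0.025, -0.025 and 0.025, which leaves -0.065, -0.108 and 0.164. With a separate TGF-β library on each side, r was -0.11 and -0.14, then -0.24 and -0.20, then 0.32 and 0.25. Each such side held 1 library, which adds noise, and part of the excess in the overlaps may come from the shared TGF-β libraries.

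Markers of other cell types were examined in the same libraries. Kidney epithelial markers lay under 1 FPKM in every library for 16 of 22 genes, leukocyte markers for 9 of 14, endothelial markers for 9 of 11 and adipocyte and chondrocyte markers for 10 of 14. The most abundant were Krt8, a keratin, at up to 685.1 FPKM, Cd14 at 55.29, Egfl7 at 23.2 and Sox9 at 22.15. Krt8 rose with siHoxc8 from 209 ± 22.4 to 665 ± 28 FPKM (1.67 ± 0.11, adjusted p = 6.24e-05), while Krt7 fell (-1.11). Of the 6 tested epithelial markers 3 rose and 1 fell with MetR (the same numbers adjusted over the list alone, camera adjusted p = 0.461). Of the 5 tested leukocyte markers 3 rose and 1 fell with MetR (the same numbers adjusted over the list alone, camera adjusted p = 0.755). Cd74, the invariant chain of antigen presentation, fell with TGF-β from 34.8 ± 2.04 to 5.73 ± 0.391 FPKM (-2.41 ± 0.16, adjusted p = 8.17e-05).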

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

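The alternatives chosen only after seeing the data were limma-voom on the recovered reads, library weights and removal of the length trend. Of 370 named gene values, 359 kept their direction and their side of the threshold under median ratio rescaling, 357 under quantile normalization, 360 with no filter on low values, 368 at a pseudocount of 0.1, 367 with limma-voom and 310 when a change of at least 2-fold was required. Of 150 gene list tests, 143 did so under median ratio rescaling, 133 under quantile normalization and 142 with the length trend removed. With limma-voom 1279 genes rose and 3630 fell with TGF-β, 4303 and 2349 with MetR, and 3484 and 1915 with siHoxc8. A fit with a replicate block gave 1279 and 3471, 4298 and 2341, and 3478 and 1946 for the same comparisons. The block ended the call of matrix glycoproteins with siHoxc8 (adjusted p = 0.0509, range 0.0193 to 0.317 over the alternatives) and 1 named gene, Cd68 with siHoxc8 (adjusted p = 0.0543, range 0.0137 to 0.188), gave that of inflammatory mediators between siHoxc8 and MetR (adjusted p = 0.04, range 0.013 to 0.232) and changed no other call among the gene list tests and the 370 named gene values. Of all genes called in the main analysis, 4543 of 4792 with TGF-β, 6462 of 6634 with MetR and 5185 of 5394 with siHoxc8 were called with the block as well. Fewer kept their call under median ratio rescaling (3409, 5510 and 4525) and under quantile normalization (3247, 5497 and 4630). The 370 named gene values were chosen partly by size of change, so they do not stand for all called genes. Deviations of libraries with the same number correlated at 0.2 between TGF-β and MetR and at -0.02 to 0.02 elsewhere, and the numbers were not taken as pairs.

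Scalings that centre the libraries evened the split of raised and lowered genes by construction. For TGF-β against control the counts were 2274 and 2140 under median ratio rescaling, 2079 and 2102 under quantile normalization, and 2358 and 2084 with the length trend removed, which also centres each library. The overlaps in the order given (raised by TGF-β and lowered by MetR, lowered and raised, the same for siHoxc8, raised by both treatments, lowered by both) were 1038, 608, 977, 820, 1071 and 1311 under median ratio rescaling. Those beyond 1.5 times were 819, 614, 844, 804 and 1139 for the same overlaps except the last under quantile normalization, and 1031, 583, 1005, 802 and, for those lowered by both, 1372 with the length trend removed. Numbers for independent lists were not computed for any of the alternatives, so whether the excess over them changed was not tested. A minimum of 2-fold, which leaves fewer genes by construction, gave 345 raised and 945 lowered genes with TGF-β, 1319 and 826 with MetR, 962 and 582 with siHoxc8, 1163 and 1580 for MetR against control, 752 and 1129 for siHoxc8 against control, and 1147 and 1151 for siHoxc8 against MetR, and overlaps of 116, 162, 124, 285, 227 and 190. With separate TGF-β libraries, in the split that lay nearer 0, the correlation of the TGF-β and MetR changes was -0.109, that of the TGF-β and siHoxc8 changes -0.201, and that of the MetR and siHoxc8 changes 0.25. Each side then holds 1 TGF-β library, which adds noise as the sharing ends, and the cause was not tested.

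Leaving out 1 library leaves its group with 1, which is assumed to vary like the other groups. Over the 8 such fits, TGF-β raised 620 to 1768 and lowered 1700 to 4530 genes, with the lowest counts without control replicate 1, MetR raised 3453 to 4780 and lowered 1799 to 2547, and siHoxc8 raised 2004 to 4304 and lowered 1148 to 2431, with the lowest counts without siHoxc8 replicate 1. Against control, MetR gave 2428 to 3933 and 2720 to 3723 and siHoxc8 1676 to 3309 and 2156 to 3891, and siHoxc8 against MetR gave 2181 to 3305 and 2440 to 4062. The 6 overlaps ran from 273 to 670, 563 to 1943, 280 to 743, 710 to 2025, 945 to 2374 and 531 to 1070, and the correlations from -0.243 to -0.15, -0.326 to -0.28 and 0.31 to 0.379. Without MetR replicate 2 the Col3a1 change with MetR was reversed (0.447), and over the fits it ran from -1.805 to 0.447, since its MetR libraries lay on either side of the TGF-β level.

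Of 150 gene list tests 59 passed camera with its preset correlation and 57 to 66 with a library left out. With an estimated correlation camera passed 0, with 6, 1, 5, 2, 2 and 2 of 25 at an unadjusted p under 0.05, and fry passed 89, as it asks another question. In the direction of camera, 38 list tests passed fry and not camera, and 9 passed camera and not fry. Among the 38 were P-TEFb and pause release genes with MetR (up, fry adjusted p = 0.00304) and interferon response genes with MetR (up, fry adjusted p = 0.00181). Matrix glycoproteins with TGF-β were among the 9 (fry adjusted p = 0.104). For the ligands, receptors and Smads with TGF-β the direction was reversed under fry. The mean of the list lay 0.052 above that of other genes, but fry, which by construction does not set a list against other genes, pointed down. The chi-square per gene between the replicates of a group was 3.57 for control, 20.96 for TGF-β, 64.65 for MetR and 3.64 for siHoxc8, all above counting error.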

Other observations

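All tests of the ribosomal protein and cell cycle genes here, and the test of scaling for the matrix genes, were chosen only after the result was seen.

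Hox genes were read by cluster, a grouping and a choice of genes made after their values were seen. In the HoxC cluster, which holds Hoxc8, 5 of 6 tested genes fell and 1 rose with MetR against TGF-β (median -1.06, and -1.90 for Hoxc8 itself), and 5 fell and 1 did not pass with siHoxc8 (median -1.20). With MetR and with siHoxc8, respectively, Hoxc6 changed by -1.16 ± 0.11 and -1.52 ± 0.11 and Hoxc9 by -1.08 ± 0.22 and -1.33 ± 0.22 (SE, n = 2 each). Hoxc4 changed by -1.04 ± 0.13 and -0.61 ± 0.13 and Hoxc5 by -0.95 ± 0.26 and -1.07 ± 0.26. The call of Hoxc9 with MetR was lost with library weights (adjusted p = 0.0774, range 0.00276 to 0.0774 over the alternatives). That of Hoxc5 with siHoxc8 was lost without TGF-β replicate 1 or siHoxc8 replicate 1 (adjusted p = 0.0616 and 0.085, range 0.00674 to 0.085 over the alternatives). Hoxc10 rose with MetR (0.34 ± 0.12) and stood at 13.7 ± 0.261 FPKM with siHoxc8 against 14.1 ± 0.635 with TGF-β. In the HoxB cluster 3 of 9 rose and 1 fell with MetR, and 1 rose and 3 fell with siHoxc8. In the HoxD cluster 2 of 7 rose and 2 fell with MetR and 3 fell with siHoxc8. Whether reads of neighbouring or antisense Hox transcripts were shared was not tested.

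Inflammatory mediators did not pass the camera test in the values as deposited, and passed it in most comparisons under some of the alternatives. With TGF-β 13 of 21 fell and 3 rose (13 and 4 adjusted over the list alone, camera adjusted p = 0.158, range 0.0157 to 0.509 over the alternatives, past the threshold under median ratio rescaling, quantile normalization, no filter on low values and removal of the length trend). The median of the list with TGF-β was -1.21, and fry, which does not set a list against other genes, pointed down (fry adjusted p = 0.00386). Il33, an alarmin, changed by -3.64 ± 0.23 and Lcn2, lipocalin 2, by -2.88 ± 0.20. With MetR 13 rose and 2 fell against TGF-β (the same numbers adjusted over the list alone, camera adjusted p = 0.0781, range 0.02 to 0.136, past it under median ratio rescaling, quantile normalization, a mean FPKM of at least 5, removal of the length trend and without MetR replicate 2). Risers were Il6 (3.11 ± 0.21), Lif (2.07 ± 0.18) and Tnfaip3 (2.05 ± 0.21). With siHoxc8 9 rose and 7 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.81). The chemokine genes Ccl2 (-3.10 ± 0.14) and Ccl7 (-2.60 ± 0.21) fell, and Il33 (2.62 ± 0.23) and Il6 (2.19 ± 0.21) rose. Between siHoxc8 and MetR 11 were lower and 4 higher with siHoxc8 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0599, and adjusted p = 0.535 with an estimated correlation, range 0.013 to 0.232 over the alternatives). That test passed at a pseudocount of 0.1, at a mean FPKM of at least 5, with median ratio rescaling, the replicate block, limma-voom, library weights or the length trend removed, and without MetR replicate 1 or siHoxc8 replicate 2. Hmox1, heme oxygenase, rose from 12.8 ± 1.24 FPKM with TGF-β to 79.4 ± 8.05 with MetR and 71.6 ± 1.16 with siHoxc8 (SD, n = 2 each). Interferon response genes, lowered by TGF-β, rose in 9 and fell in 5 of 23 cases with MetR (11 and 5 adjusted over the list alone, camera adjusted p = 0.914), with Ifit2 at 2.74 ± 0.12 and Ifi35 at -1.40 ± 0.19.

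Matrix genes differed between the MetR libraries, with 41 of 43 higher in replicate 1, by a median of 0.73 on the log2 scale (0.57 to 0.84, 95% bootstrap interval over genes), and 11 lay on opposite sides of the TGF-β mean in the 2 libraries. Gene length and scaling are argued against as the cause, since the median was 0.68 (0.54 to 0.79) with each library's length trend removed and that of all tested genes was -0.074. A stronger response in replicate 2 should place 75% or more of these genes farther from the TGF-β mean there, on the same side. Of these genes 41.9% (18 of 43, exact Clopper-Pearson interval 27% to 57.9%) were so placed, beside 54% of all tested genes. The interval counts genes as independent and does not cover variation between libraries. With 1 library on each side, the shortfall does not exclude a stronger response. The lists that passed camera with MetR at its preset correlation went both ways, with the larger median change in replicate 2 for ATF4 targets (0.69 and 1.30 in replicates 1 and 2), crosslinking (-0.38 and -0.99), cholesterol (-1.01 and -1.28), histone methylation (0.49 and 0.62), immediate early (0.82 and 0.85) and contractile genes (-0.91 and -0.93), and in replicate 1 for ribosomal protein (-1.34 and -1.19), p53 (0.70 and 0.45), glycolysis (-0.48 and -0.37), chaperone (-0.32 and -0.20) and cell cycle genes (-0.71 and -0.68). No other biological explanation was tested, as both libraries belong to 1 group, and a difference in culture, density or time remains open.

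Ribosomal protein genes fell with MetR by a median of -1.26, and short length could give such a pattern, but against their 20 nearest genes in length and expression the median difference was -0.94 (-1.15 to -0.74), where the matched genes had a median of -0.28. Scaling and a single MetR library are argued against as well, as the median closest to 0 among the scalings was -1.07, and the 2 MetR libraries had -1.34 and -1.19. Relative to the control mean, the median was -0.47 and -0.17 in the TGF-β libraries and -1.72 and -1.55 in the MetR libraries. That methionine restriction lowers these transcripts is a hypothesis found and tested on the same libraries. Reads shared with near-identical copies and the change of medium remain open, since no table here separates them.

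Cell cycle genes were higher with siHoxc8 than with TGF-β alone by a median of 1.79, and at least 1.60 under any scaling tried, which argues against scaling as the cause. Loss of the TGF-β effect alone would bring these genes back to the level of cells without TGF-β at the same time. Over both siHoxc8 libraries and all scalings they lay at least 0.42 above the control level. The titles of the control libraries give no time, so the control level may not be that level. The values therefore do not decide whether loss of the TGF-β effect was the only change. The control libraries were not labelled as transfected, so loss of the TGF-β effect together with an effect of transfection remains open. The control libraries differed by up to 0.06, which may be technical spread alone, the TGF-β libraries lay at -1.42 and -1.17, and against control 19 of 38 genes passed upward (adjusted p = 0.777 with an estimated correlation). Transfection cannot be told apart from loss of Hoxc8, because 0 RNA-seq libraries had a control siRNA. The interferon list, which transfection may raise, had a median of 0.16 as deposited and 0.01 after median ratio rescaling. With siHoxc8 against TGF-β 7 of its 23 genes rose and 4 fell. The list did not pass camera (adjusted p = 0.81), while fry pointed up (fry adjusted p = 0.00677), so a reaction to the siRNA was neither shown nor excluded. A role of Hoxc8 in holding back proliferation under TGF-β is therefore a hypothesis that these libraries leave open.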
